A study of Homo sapiens with 6 samples.

How the data were processed

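Total RNA of MCF-10A cells, 3 vector control and 3 PDEF samples harvested 26 h after retroviral infection, was labelled with biotin and hybridised to single-colour Affymetrix expression arrays, 1 array per sample, per the labels' protocols. Each probe set on such an array summarises several short probes. The authors deposited 1 table of log2 expression per probe set and array, and the submitters' processing notes name RMA, which corrects the background, normalizes by quantiles and summarises probes on the log2 scale, and limma, with no version for either. The scanner files were not used here, so the background step could not be changed, and RMA gives no detection calls: a low level cannot be separated from background, and the changes of dim probe sets are compressed towards 0. The arrays' medians and quartiles lay close together, as the report gives them.

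Groups came from the titles and treatment labels, and every column of the table was matched to its sample. The table held 54675 probe sets, of which 62 control probe sets were left out of the tests and 54613 were tested. Gene names came from the platform annotation supplied with the table, brought up to date by Entrez identifier through a table of RefSeq genes (assembly GCF_000001405.40); 41037 of the 41091 probe sets with 1 gene were found there. A further 1801 probe sets had several genes and named none, and 11721 had no gene named here. Genes absent from the names used here were not analysed here. No genome positions are given, since the table states no build; the gene table served only for names and for which genes neighbour each other. Of probe sets that name 1 gene, the one with the highest mean over the 6 arrays represented it, which gave 19775 genes. Probe sets whose identifiers end in _x_at or _s_at can bind several transcripts, so they were left out in an alternative. A gene with no other probe set then had no value, so counts in that setting cover fewer genes.

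Differences are PDEF minus vector control on the log2 scale, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all 54613 probe sets and a threshold of 0.05. SE is the moderated standard error, intervals are at 95%, and folds are 2 raised to the size of the log2 difference. The 20 gene lists were tested with camera at a preset correlation of 0.01 between genes, beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the 20 lists. Single values between 3 and 3 arrays had an exact two-sided permutation test, which cannot give a p under 0.1. The lists were luminal, basal, goblet and secretory, junction, mesenchymal, S phase, mitosis, interferon, endoplasmic reticulum stress, EGF receptor and ERK, cytokine, apoptosis, keratinocyte, cholesterol, p53, hypoxia and ETS family genes, with fibroblast, leukocyte and endothelial markers for cells that the culture should lack.

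The lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. The rule took SPDEF, then the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, then from each list up to 4 members past the threshold with the largest change. Other members, among them all that did not pass, were chosen after their values were seen.

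The fit was tested on simulated data with the spread of the real arrays and 54613 probe sets for the comparison of PDEF with control. Of planted log2 changes of 0.5, 60% were recovered, and of those of 1, 2 and 3, 100%. Of 195 calls 15 were false, camera called the planted list and 0 of 39 unchanged ones, and 2 of 20 random sets of genes passed the test of neighbours at 0.05. The simulated noise was independent between genes. Camera was therefore not tried at correlations as estimated in the real lists, 0.62 for the mitosis list, and its calls there are not checked by this simulation.

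The alternatives were a block for the replicate number, each array left out in turn, dim probe sets left out, a trended and robust prior variance, array weights, quantile normalization, median centring, _x_at and _s_at probe sets left out, the mean of a gene's probe sets, a test against a fold of 1.2, ordinary t statistics without a shared prior, and the other set tests. The closing section gives their effect.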

Results

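MCF-10A is an established, non-tumorigenic line of human mammary epithelial cells that grows in culture with epidermal growth factor (EGF) among its usual supplements; here the cells were kept in the usual medium with EGF left out. The cells were infected with a retrovirus that carried either an empty vector or PDEF, the transcription factor of the ETS family whose gene is now named SPDEF, and total RNA was taken 26 h after infection. RNA from 3 vector control and 3 PDEF samples was measured on 6 single-colour arrays, 1 per sample, as log2 expression of 54613 probe sets after 62 control probe sets were set aside. The labels call the samples biological replicates without saying how they were kept apart, so p-values measure the spread between these samples. The number of arrays limits the precision. Array medians lay between 3.73 and 3.78 and upper quartiles between 5.85 and 5.89. Over probe sets, arrays of a group correlated with r of 0.995 to 0.996, and arrays of different groups with r of 0.986 to 0.988.

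SPDEF itself was measured before any other gene, since it was the gene introduced. Its brightest probe set, 214404_x_at, rose from 6.02 ± 0.07 in the vector control to 12.35 ± 0.07 in the PDEF samples (log2, SD, n = 3 each), a difference of 6.33 with an SE of 0.08 and a fold of 80.3 (adjusted p = 5.87e-10, limma with Benjamini-Hochberg adjustment). Probe set 220192_x_at rose by 6.87 and 213441_x_at by 4.66. The differences of 213442_x_at and 214403_x_at, 0.02 and 0.09, did not pass the test. All 5 belong to the _x_at type, which can bind related transcripts, and where each lies relative to the introduced sequence was not analysed here. No value of the 3 PDEF arrays overlapped the controls for the brightest probe set, for which an exact two-sided permutation test gave p = 0.1, the smallest it allows with 3 against 3.

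**Figure D1:**
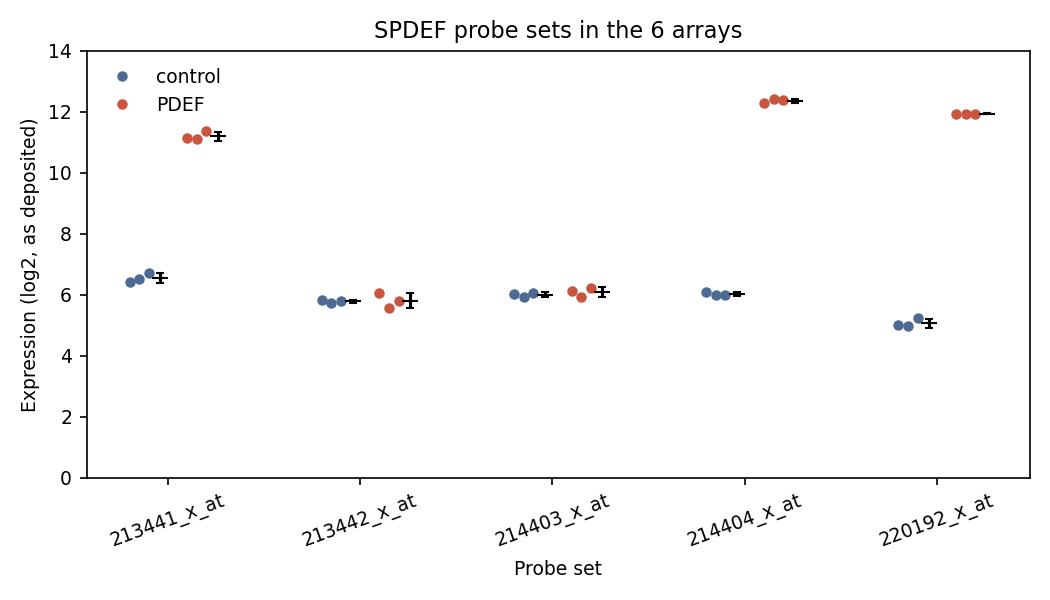
Expression (log2, as deposited) of the 5 SPDEF probe sets in the 3 vector control (blue) and 3 PDEF (red) arrays; points are arrays, bars beside them the mean and SD. PDEF values of 214404_x_at average 12.35 against 6.02 in the controls, while 213442_x_at and 214403_x_at lie at similar levels in both groups.

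The main comparison asked which transcripts differ in level between PDEF-expressing and vector control MCF-10A cells. After SPDEF, the largest rises were those of AZGP1, a secreted zinc-binding glycoprotein, from 3.50 ± 0.26 to 9.32 ± 0.07 (log2, SD, n = 3 each), and of C9orf152, by 5.75 (SE 0.11). Next came KLK10 (5.06), KLK7 (4.88), HPD (4.85), CDC42EP5 (4.80), SPRR1B (4.60), KLK8 (4.45), PLCB4 (4.45), KLK5 (3.97) and BHLHE41 (3.95). HPD is an enzyme of tyrosine breakdown, the KLK genes encode secreted serine proteases, SPRR1B a precursor of the cornified envelope, and BHLHE41 a repressor of clock genes. The largest falls were those of MAP7D2 by 3.94 (SE 0.12), RGS2, a regulator of G protein signalling, by 3.80 (SE 0.08), and DCN, the matrix proteoglycan decorin, by 3.59 (SE 0.09). They were followed by ADH1B (-3.21), GREB1 (-3.05), PNLIPRP3 (-3.03), KRT14 (-3.03), IFI44L (-2.87), RIPOR2 (-2.76), SLC7A2 (-2.76), the Wnt inhibitor DKK1 (-2.73) and the non-coding LINC03125 (-2.41). Adjusted p for the rises of AZGP1 and BHLHE41 was 7.96e-09 and 4.88e-06, and for the falls of MAP7D2 and LINC03125 9.97e-08 and 4.64e-05 (limma with Benjamini-Hochberg adjustment). BHLHE41 rose on 2 of its 4 probe sets, and its value with _x_at and _s_at probe sets left out was 0.02 (adjusted p = 0.951, lowest of the alternatives 5.1e-09). In that setting ADH1B fell by 0.71 (adjusted p = 0.0265).

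With 1 probe set per gene, 2658 of 19775 genes (13.4%) passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment over all probe sets), 1475 higher and 1183 lower with PDEF. Of these, 301 were over 2-fold higher and 153 over 2-fold lower. Among all 54613 probe sets, 5350 passed, 2865 higher and 2485 lower, and 11876 had an unadjusted p under 0.05. The values of both groups did not overlap for 6462 genes, 32.7% of those measured, where chance gives 10%. The count of probe sets was 3529 without control replicate 1, and the lower ones numbered 1555 without it and 1651 without control replicate 3. Tested against a fold of 1.2 the count was 1736, with ordinary t statistics 2409, and with _x_at and _s_at probe sets left out 3168. Of 1710 changed genes with several probe sets, 2 had another probe set that passed in the opposite direction.

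**Figure D2:**
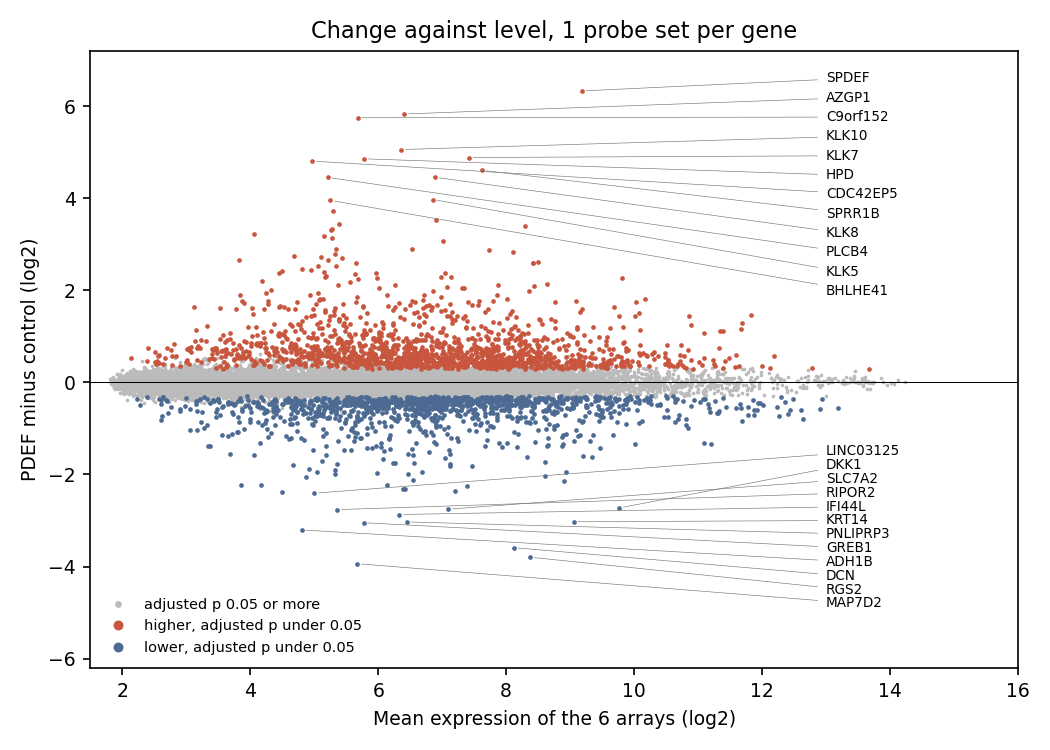
Difference PDEF minus control (log2) against the mean of the 6 arrays (log2), each point a gene represented by 1 probe set; red genes were higher and blue genes lower at an adjusted p of 0.05, grey ones did not pass, and names mark the 12 largest rises and 12 largest falls. SPDEF lies highest at 6.33 and MAP7D2 lowest at -3.94.

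Among markers of the mammary epithelium, more luminal ones rose than fell, and more basal ones fell than rose. Of 31 measured luminal epithelial markers, 8 rose and 1 fell, and adjusted over the list alone 13 rose and 1 fell. AGR2, a disulfide isomerase of secretory cells, rose 7.4-fold (log2 2.89, SE 0.09), the epithelial ETS factor ELF3 7.14-fold (2.84, SE 0.08), CD24 2.72-fold (1.45, SE 0.09) and the milk protein LTF 2.37-fold (1.25, SE 0.14). MYB (1.23), KRT18 (1.16), XBP1 (0.90) and MUC1 (0.40) also rose, and TBX3 fell by 0.42. Among the members that did not pass were the estrogen receptor gene ESR1 at -0.22, GATA3 at 0.29, FOXA1 at 0.21 (its other probe set passed at 0.52) and KRT8 at 0.20. Of 25 measured basal and myoepithelial markers, 10 fell and 2 rose, and adjusted over the list alone 12 fell and 3 rose. The basal keratin KRT14 fell 8.16-fold (-3.03, SE 0.12), the peptidase MME 2.43-fold (-1.28, SE 0.10) and TRIM29 1.68-fold (-0.75, SE 0.09). KRT5 (-0.73), JAG2 (-0.74), the integrin chains ITGB4 (-0.58) and ITGA6 (-0.48), CAV1 (-0.54), DST (-0.51) and EGFR (-0.44) fell too. The oxytocin receptor OXTR rose by 2.01 (SE 0.12) and the laminin chain LAMB3 by 0.74, while the contractile genes ACTA2 (0.26), MYLK (0.09) and CNN1 (-0.19) did not pass. Camera, limma's test of a list against other genes, called the luminal list up (adjusted p = 6.07e-05; adjusted p = 0.0736 with an estimated correlation) and the basal list down (adjusted p = 0.00720; adjusted p = 0.471 with an estimated correlation). With _x_at and _s_at probe sets left out, 4 luminal markers rose with a list median of -0.01 against 0.21. CD24, KRT18 and LTF had no value in that setting, so their rises were not retested. There 6 basal markers fell, MME had no value, and camera no longer called the list (adjusted p = 0.0598, lowest of the alternatives 0.00178). TBX3 did not pass without control replicate 2 or 3 or without PDEF replicate 1 or 2, nor as the mean of its probe sets.

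**Figure D3:**
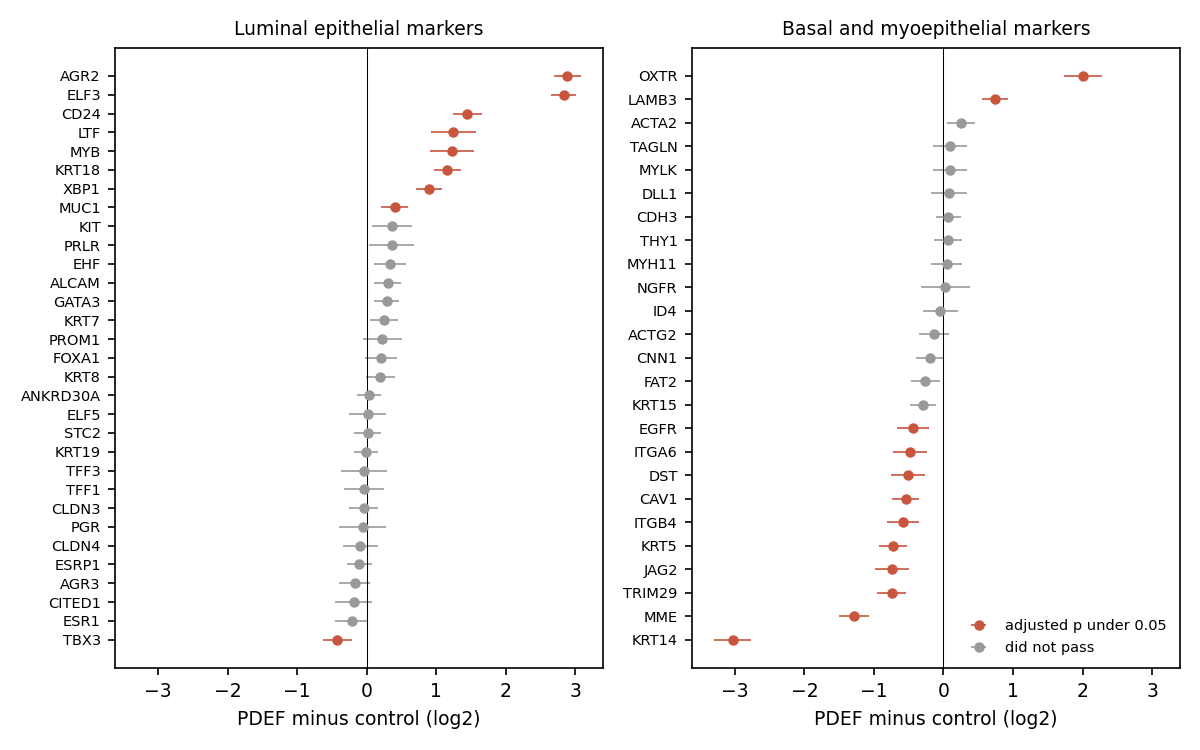
Difference PDEF minus control (log2) with its 95% confidence interval for each measured luminal marker and each measured basal or myoepithelial marker, 3 arrays per group; red markers passed an adjusted p of 0.05 and grey ones did not. AGR2 (2.89) and ELF3 (2.84) lead the luminal rises, and KRT14 lies lowest among basal markers at -3.03.

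Secretory genes rose in part. Of 32 goblet and secretory epithelium genes, 10 rose and 0 fell, and adjusted over the list alone 11 rose and 1 fell (limma; 2 fell at an unadjusted p under 0.05, and 1 passed without control replicate 3, without PDEF replicate 2 and with dim probe sets left out). CREB3L4, a membrane-bound transcription factor, rose 10.5-fold (log2 3.40, SE 0.08), the secretoglobin SCGB2A2 9.28-fold (3.21, SE 0.17) and WFDC2 4.84-fold (2.28, SE 0.14), besides AGR2. LCN2 (1.41), SCGB2A1 (0.77), MUC16 (0.73) and SLPI (0.54) rose as well, SCGB2A1 from 2.69 to 3.45, under the arrays' medians in both groups. Control levels lay above the arrays' highest median for 14 of the 32 genes, and low levels cannot be separated from background. Goblet cell genes that did not pass included the secreted mucins MUC5AC (-0.45) and MUC5B (0.03), the trefoil factor TFF3 (-0.03) and the transcription factor FOXA3 (-0.00). The list was called up by camera (adjusted p = 0.00110; adjusted p = 0.0736 with an estimated correlation), with a median of 0.03.

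Genes of the endoplasmic reticulum stress response, which serves protein folding in the secretory pathway, rose more often than they fell. Of 27 measured, 8 rose and 1 fell, and adjusted over the list alone 13 rose and 1 fell. The stress sensor ERN1 rose 2.08-fold (log2 1.06, SE 0.11), the chaperone DNAJB9 2.08-fold (1.06, SE 0.08), ASNS 1.96-fold (0.97, SE 0.08) and the transcription factor XBP1 1.87-fold (0.90, SE 0.08). ERN1 rose on 1 of its 3 probe sets (mean over them 0.40) and XBP1 on 1 of its 2 (mean 0.47). TRIB3 (0.88), HERPUD1 (0.48), HSPA5 (0.48) and PDIA4 (0.41) also rose, whereas ATF4 (-0.18), DDIT3 (0.11) and ATF3 (0.02) did not pass. Camera called the list up (adjusted p = 3.91e-05; adjusted p = 0.0736 with an estimated correlation). The single fall, of CRELD2 by 0.32, did not pass when any of the 6 arrays was left out or under median centring, 2 members fell with a trended and robust prior, and the other ASNS probe set gave -0.23 (adjusted p = 0.155, lowest of the alternatives 3.47e-07). With _x_at and _s_at probe sets left out the median of the list was 0.08 against 0.25.

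The ETS family, to which SPDEF itself belongs, was compared as a list of its other members. Of 26 measured, ELF3 rose and ELF4 fell (-0.43, SE 0.08), and adjusted over the list alone 4 rose and 1 fell. Camera did not call the list (adjusted p = 0.448). In place of 1 member, 2 rose without PDEF replicate 1, with the replicate block, array weights or median centring, 3 with the mean of a gene's probe sets, and 4 with dim probe sets left out or a trended and robust prior.

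Genes of epithelial adhesion moved both ways. Of 29 measured epithelial adhesion and junction genes, 6 rose and 7 fell, and adjusted over the list alone 7 rose and 8 fell. The tight junction protein MARVELD3 rose 4.5-fold (log2 2.17, SE 0.14) and the adhesion molecule EPCAM 2.71-fold (1.44, SE 0.09). CLDN1, another tight junction protein, fell 2.98-fold (-1.57, SE 0.13) and the desmosome-associated PPL 1.8-fold (-0.85, SE 0.09). CLDN7 (0.79) and TJP3 (0.84) rose, and the desmosomal genes DSG3 (-0.83), PKP2 (-0.52), DSP (-0.39) and PKP3 (-0.35) fell. E-cadherin, CDH1, did not pass at -0.25. Camera did not call the list (adjusted p = 0.957). The number that fell was 4 without control replicate 1, without control replicate 3, without PDEF replicate 1 and with _x_at and _s_at probe sets left out.

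Mesenchymal genes were likewise split. Of 34 measured mesenchymal and EMT (epithelial-mesenchymal transition) genes, 8 rose and 9 fell, and adjusted over the list alone 9 rose and 10 fell. N-cadherin, CDH2, rose 4.12-fold (log2 2.04, SE 0.11), TGFB2 3.74-fold (1.90, SE 0.19), the urokinase receptor PLAUR 3.37-fold (1.75, SE 0.13) and TNC 3.03-fold (1.60, SE 0.09). The matrix genes FN1 (-1.46) and SPARC (-1.32), the transcription factors ZEB2 (-1.13) and TWIST1 (-0.64), TGFB1 (-0.83) and vimentin, VIM (-0.45), fell. SNAI2 (-0.33), ZEB1 (-0.28, though 1 of its 4 probe sets fell) and SNAI1 (-0.11) did not pass. Camera did not call the list (adjusted p = 0.919).

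More genes of cell division rose than fell with PDEF. Of 34 mitosis genes, 25 rose and 0 fell by limma, and adjusted over the list alone 30 rose and 0 fell (0 fell at an unadjusted p under 0.05 as well), with a list median of 0.55. The kinetochore gene NUF2 rose 2.28-fold (log2 1.19, SE 0.24), HMMR 2.26-fold (1.18, SE 0.19), and the checkpoint kinases TTK 2.13-fold (1.09, SE 0.15) and BUB1 1.97-fold (0.98, SE 0.16). BUB1 passed on 1 of its 5 probe sets, and the mean over them was 0.27. CDC20 (0.92), MKI67 (0.67), AURKA (0.59) and CDK1 (0.59) rose, while PLK1 (0.27), FOXM1 (0.27) and CCNB1 (0.29) did not pass. Of 33 measured DNA replication and S phase genes, 9 rose and 0 fell by limma (4 fell at an unadjusted p under 0.05), and adjusted over the list alone 10 rose and 2 fell. UHRF1, a factor of DNA methylation maintenance, rose 2.73-fold (1.45, SE 0.11), followed by GINS3 (0.63, SE 0.11), TK1 (0.59, SE 0.13) and RFC4 (0.54, SE 0.12), and the replicative helicase genes MCM2 (0.28), MCM4 (-0.18) and MCM6 (0.01) did not pass. Camera called the mitosis list up (adjusted p = 1.50e-14; adjusted p = 0.329 with an estimated correlation) and the S phase list up (adjusted p = 0.00471; adjusted p = 0.471 with an estimated correlation). Mitosis genes that rose numbered 15 without control replicate 1, 14 without PDEF replicate 1 and 15 without PDEF replicate 2, and S phase genes that rose 3 without control replicate 1 and 2 without PDEF replicate 1. Without control replicate 2, with the replicate block and with the mean of a gene's probe sets 1 S phase gene fell, and 2 with dim probe sets left out; TK1 did not pass without control replicate 1 or PDEF replicate 1, nor RFC4 without control replicate 1 or 2 or PDEF replicate 1.

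The largest rises among the members of the 20 lists were those of keratinocyte differentiation genes. Of 34 measured keratinocyte differentiation genes, 11 rose and 4 fell, and adjusted over the list alone 12 rose and 5 fell. KLK10 rose 33.2-fold (SE 0.10 on the log2 scale), KLK7 29.5-fold (SE 0.09), SPRR1B 24.3-fold (SE 0.11) and KLK8 21.9-fold (SE 0.10). KLK5, SPRR1A (3.53), KLK6 (3.30), KRT13 (2.44), SERPINB3 (2.39) and SERPINB4 (1.64) rose too. The calcium-binding S100A8 (-1.27) and S100A9 (-0.96), the cross-linking enzyme TGM1 (-0.96) and the suprabasal keratin KRT10 (-0.72) fell. Involucrin, IVL (0.10), filaggrin, FLG (-0.18), and KRT1 (0.02) did not pass. Camera called the list up (adjusted p = 0.00363; adjusted p = 0.246 with an estimated correlation), with a median of 0.02. With _x_at and _s_at probe sets left out, 6 rose and 2 fell and the list was no longer called (adjusted p = 0.0598, lowest of the alternatives 9.62e-05); related KLK, SPRR, KRT and SERPINB genes can share signal on such probe sets. Without them KLK10 rose by 1.17 and KLK8 by 2.99, and KLK5 had no value. KLK7, KLK6 and SPRR1B stood on probe sets of neither type. Over the alternatives the rise of KLK7 ranged from 4.84 to 4.95 and that of SPRR1B from 4.51 to 4.66.

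Chemokines led the cytokine and NF-kappaB response genes, of which 31 were measured. Of these, 11 rose and 3 fell, and adjusted over the list alone 13 rose and 5 fell. The neutrophil-attracting CXCL2 rose 6.07-fold (log2 2.60, SE 0.09), CXCL3 5.76-fold (2.53, SE 0.09), CXCL1 3.63-fold (1.86, SE 0.13) and CXCL8 3.01-fold (1.59, SE 0.11). TNFAIP2 (1.18), CSF1 (0.83) and CCL20 (0.80) rose, and complement C3 (-1.31), IL1A (-0.86) and IL1B (-0.63) fell. IL6 (0.18), TNF (0.06) and NFKBIA (-0.07) did not pass. Camera called the list up (adjusted p = 0.00110; adjusted p = 0.329 with an estimated correlation). The number that rose was 7 without PDEF replicate 3 and 7 with _x_at and _s_at probe sets left out, where CXCL2 rose by 1.34 and CXCL8 had no value.

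Interferon response genes changed both ways. Of 37 measured, 7 rose and 6 fell, and adjusted over the list alone 9 rose and 7 fell. IFI44L fell 7.31-fold (log2 -2.87, SE 0.15) and IFI44 3.49-fold (-1.80, SE 0.13), while PSMB9, a subunit of the immunoproteasome, rose 2.18-fold (1.13, SE 0.08) and the RNA sensor IFIH1 2.08-fold (1.06, SE 0.10). BST2 (-0.76), IFITM1 (-0.59) and IFI6 (-0.57) fell, DDX60 (0.68) and IFIT2 (0.52) rose, and ISG15 (0.37) and MX1 (0.02) did not pass. Camera did not call the list (adjusted p = 0.448). The other IFI44 probe set gave -0.25 (adjusted p = 0.393, lowest of the alternatives 4.32e-07), and 4 members rose with _x_at and _s_at probe sets left out.

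Since EGF was left out of the medium, response genes of its receptor and of ERK signalling were compared. Of 31 measured, 6 rose and 6 fell, with the same counts adjusted over the list alone. IER3 rose 3.51-fold (log2 1.81, SE 0.10) and the receptor ligand TGFA 1.56-fold (0.64, SE 0.10), whereas JUN fell 2.96-fold (-1.57, SE 0.10) and FOS 2.74-fold (-1.45, SE 0.10). MYC (-0.55) and DUSP1 (-0.48) fell, EGR1 (0.36) and FOSL1 (0.36) rose, and DUSP6 (0.21, though 1 of its 3 probe sets rose), SPRY4 (0.11) and CCND1 (0.08) did not pass. Camera did not call the list (adjusted p = 0.919). JUN fell by 0.52 (adjusted p = 0.0364) with _x_at and _s_at probe sets left out.

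Apoptosis, p53 and hypoxia genes changed in both directions. Of 30 measured apoptosis and survival genes, 4 rose and 2 fell, and adjusted over the list alone 5 rose and 2 fell. The death ligand TNFSF10 rose 2.97-fold (log2 1.57, SE 0.12), APAF1 rose by 0.66 (SE 0.10) and BID by 0.54 (SE 0.08), and HRK fell by 0.56 (SE 0.12). Of 27 measured p53 response genes, 4 rose and 2 fell, and adjusted over the list alone 5 rose and 3 fell. SESN1 fell by 0.94 (SE 0.09), PLK2 rose by 0.92 (SE 0.10), DDB2 by 0.75 (SE 0.08) and RRM2B by 0.52 (SE 0.09), and the cell cycle inhibitor CDKN1A did not pass at 0.15. Of 31 measured hypoxia and glycolysis genes, 6 rose and 3 fell, and adjusted over the list alone 8 rose and 8 fell. EGLN3 rose by 1.60 (SE 0.11), ANKRD37 by 1.28 (SE 0.10), the glycolytic enzyme HK2 by 1.06 (SE 0.09) and the angiogenic factor VEGFA by 0.77 (SE 0.10), and NDRG1 fell by 0.68. Camera called none of these lists (adjusted p = 0.250 for apoptosis, 0.462 for p53 and 0.831 for hypoxia). Their counts stand beside 13.4% of all genes that passed, and beside 6103 of 27307 probe sets with dim ones left out. The other apoptosis gene that fell, BNIP3L (-0.34, named after its values were seen), did not pass when any of the 6 arrays was left out, nor HRK without control replicate 2 or 3 or PDEF replicate 1 or 2, so that 0 apoptosis genes fell there by limma (2 to 4 at an unadjusted p under 0.05) and 1 without control replicate 1 or PDEF replicate 3 or under median centring. In place of 3 hypoxia genes, 1 fell when any array but PDEF replicate 3 was left out, 5 with dim probe sets left out, 6 with the mean of a gene's probe sets, and 10 with a trended and robust prior, where 10 rose. With _x_at and _s_at probe sets left out 2 apoptosis genes rose, 0 p53 response genes fell by limma (1 at an unadjusted p under 0.05) and BID gave 0.13 (adjusted p = 0.474, lowest of the alternatives 0.000449). SESN1 had no value in that setting, so its fall was not retested. The mean of the APAF1 probe sets was 0.34 (adjusted p = 0.128, lowest 0.0014).

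More genes of cholesterol synthesis fell than rose with PDEF. Of 19 measured, 8 fell and 1 rose, and adjusted over the list alone 12 fell and 1 rose, with a list median of -0.34. Lanosterol synthase, LSS, fell 1.91-fold (log2 -0.93, SE 0.11), squalene epoxidase, SQLE, 1.57-fold (-0.65, SE 0.10), DHCR7 1.52-fold (-0.60, SE 0.09) and ACAT2 1.49-fold (-0.57, SE 0.08). MVD (-0.55), EBP (-0.53), NSDHL (-0.51) and MSMO1 (-0.43) fell too, and the sterol reductase TM7SF2 rose by 0.41. HMGCS1 (-0.37) and the regulator SREBF2 (-0.27) did not pass. Camera called the list down (adjusted p = 1.89e-06; adjusted p = 0.0736 with an estimated correlation). With _x_at and _s_at probe sets left out 5 fell and 0 rose by limma (0 at an unadjusted p under 0.05), and 13 fell with a trended and robust prior. ACAT2 and DHCR7 had no value with those probe sets left out.

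Markers of other cell types, which a culture of an epithelial line should lack, were compared as a check. Of 15 fibroblast markers, DCN fell 12-fold and MFAP5 (0.75, SE 0.12) and COL6A3 (0.66, SE 0.11) rose, with the same counts adjusted over the list alone, and the collagen genes COL1A2 (-0.15) and COL3A1 (0.18) did not pass. Of 14 measured leukocyte markers, CD14 rose by 1.35 (SE 0.09) and CSF1R by 0.48 (SE 0.10), 3 rose adjusted over the list alone, and the pan-leukocyte PTPRC did not pass at -0.01, though 1 of its 5 probe sets rose. Of 14 endothelial markers, PECAM1 rose by 1.80 (SE 0.12) and KDR by 0.42 (SE 0.12), with the same counts adjusted over the list alone, and CDH5 (0.07) and VWF (-0.09) did not pass. The mean over the 5 PECAM1 probe sets, 3 of which rose, was 0.97. Camera called none of the lists (adjusted p = 0.957, 0.919 and 0.804). Control levels lay above the arrays' highest median for 5 fibroblast, 4 leukocyte and 9 endothelial markers, and 4 fibroblast markers and 1 leukocyte marker also stand in another list. KDR did not pass when any of the 6 arrays was left out, with the replicate block (adjusted p = 0.0741) or with _x_at and _s_at probe sets left out (adjusted p = 0.0513, lowest of the alternatives 0.0243), nor CSF1R without control replicate 3 or PDEF replicate 3, so that 1 leukocyte marker rose there and 1 endothelial marker in each of those 8 fits. Fibroblast markers that rose numbered 1 with _x_at and _s_at probe sets left out. With dim ones left out 0 rose (limma, 0 at an unadjusted p under 0.05), but MFAP5 and COL6A3 were themselves left out as dim and not tested. With _x_at and _s_at probe sets left out MFAP5 gave 0.23 (adjusted p = 0.258, lowest of the alternatives 0.000881).

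**Figure D4:**
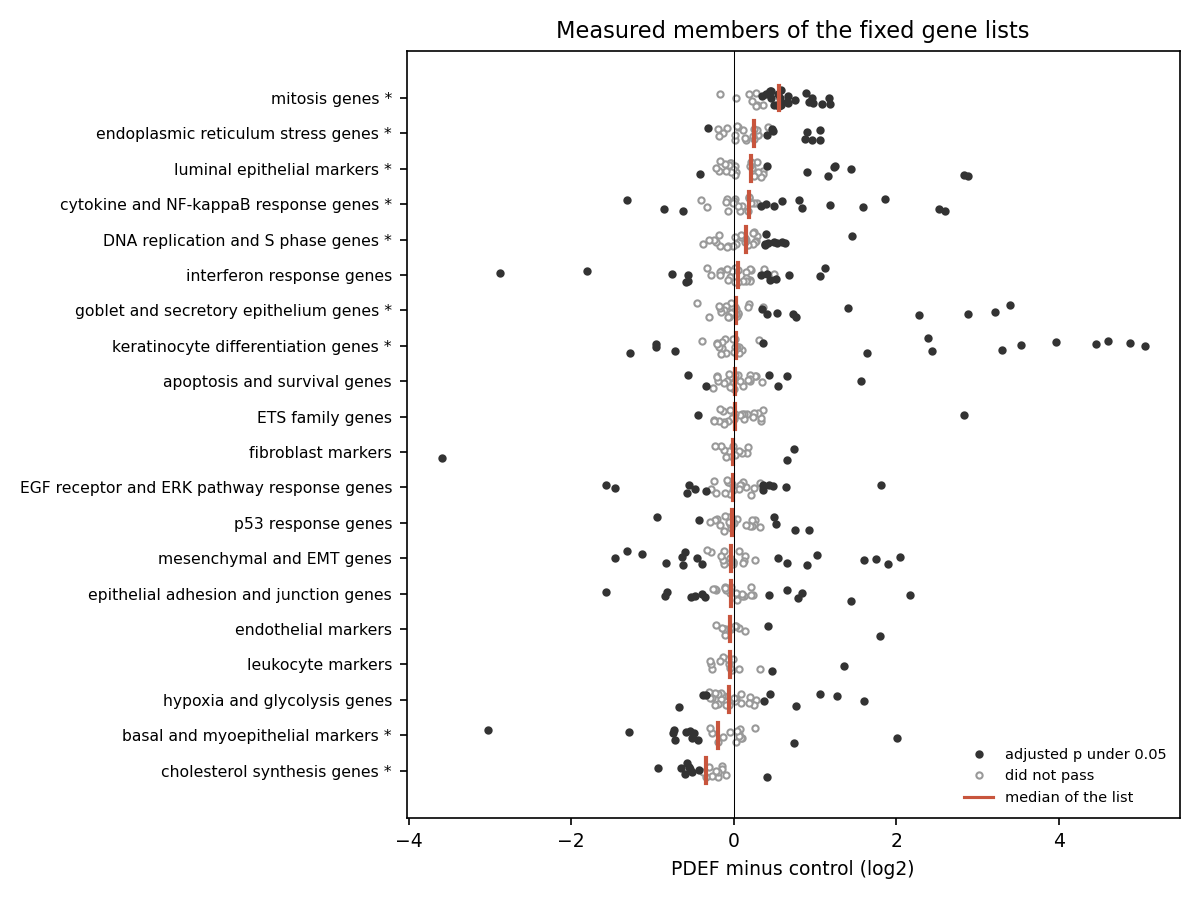
Difference PDEF minus control (log2) of every measured member of the 20 gene lists; filled points passed an adjusted p of 0.05, open points did not, red bars are list medians, vertical scatter within a list only separates points, and an asterisk marks lists that camera called with a preset correlation. The mitosis list has the highest median, 0.55, and cholesterol synthesis the lowest, -0.34.

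Camera thus called 9 of the 20 lists with the preset correlation of 0.01 between genes, 7 up and 2 down, and 0 with a correlation estimated from these arrays (4 at an unadjusted p under 0.05). The called lists share members, so their calls are not independent. Another list also held 12 of 31 luminal markers, 6 of 32 secretory genes and 1 of 27 endoplasmic reticulum stress genes. By fry, which asks whether a list's own genes move one way on balance and makes no comparison with other genes, 13 passed, and all 20 passed its test for changes in either direction. List median, mean and test differed in sign for the junction list (median -0.03, mean 0.05, camera up), the mesenchymal list (-0.03, 0.07, down), interferon (0.06, -0.04, up), p53 (-0.02, 0.06, up), hypoxia (-0.06, 0.09, up), fibroblast (-0.01, -0.16, up), leukocyte (-0.05, 0.06, up) and endothelial markers (-0.04, 0.11, up). For the EGF receptor list the median and mean were both -0.01 while the camera direction was up.

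Signs of RNA quality were compared between the groups beside these changes. The 3' minus 5' difference of the actin control probe sets was 1.13 ± 0.17 in the controls and 1.16 ± 0.25 with PDEF (log2, SD, n = 3 each; exact two-sided permutation test, p = 1). The same difference for GAPDH was 0.23 ± 0.03 and 0.19 ± 0.08 (exact p = 0.4), and the spike-in transcripts averaged 10.47 ± 0.12 and 10.55 ± 0.07 (exact p = 0.3). With 3 against 3 such a test cannot give a p under 0.1.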

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

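The Affymetrix control probe sets, left out of the tests on genes, held a difference between the groups. Of the 62, 5 passed an adjusted p of 0.05 between PDEF and vector control (limma with Benjamini-Hochberg adjustment), no larger a share than the 9.8% of the 54613 tested probe sets. Of these 5, 3 were higher and 2 lower with PDEF. The lower ones measure the 3' end and the middle of the actin transcript, at -0.30 (SE 0.06, adjusted p = 0.0261) and -0.32 (SE 0.06, adjusted p = 0.0156). Its 5' probe set gave -0.33 (SE 0.11, adjusted p = 0.183). No explanation was tested. Single arrays were not tested for standing apart from their group of 3, and the design holds 1 contrast, so no effect could be compared between settings of the study.

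Of the 10 ways to split the 6 arrays into 3 and 3, the real one gave 5350 changed probe sets and 1 split, itself, gave as many. The highest of the others gave 0 by limma, and at most 2435 at an unadjusted p under 0.05, against 11876 for the real one. With 10 splits no share under 0.05 can be had.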

How the results depend on the processing

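Probe sets that passed numbered 5350 in the main setting. With an array left out in turn they numbered 3529 to 4373 (1974 to 2441 higher and 1555 to 1975 lower), from 5 arrays. With _x_at and _s_at probe sets left out they numbered 3168 (1622 higher, 1546 lower) of 39114 tested, 3166 of them shared with the main setting. Of the main calls, 3341 were still tested there. Testing against a fold of 1.2 left 1736 (1068 higher, 668 lower), and ordinary t statistics, which share no prior spread, 2409 (1318 higher, 1091 lower). The count stayed within 1.5 times with dim probe sets left out (6103), a trended and robust prior (6894), array weights (5641), quantile normalization (5478) and median centring (5260, of which 58.6% were higher against 53.6%). SPDEF kept a rise of 6.30 to 6.37 with an array left out and of 3.59 as the mean of its probe sets, and had no value without the _x_at type. Lists called by camera fell from 9 to 0 with an estimated correlation (4 at an unadjusted p under 0.05), while fry gave 13. The labels state no pairing by replicate number, and the main fit used none. Yet same-numbered arrays deviated together with correlations of 0.09, 0.14 and 0.13, against -0.12 to -0.02 for unlike numbers. Each sample correlated best with its own number, a weak hint of pairing from the data and not the design. With 3 arrays per group few matchings exist, so chance can also put the numbered one first. The replicate block gave 5736 probe sets (3111 higher, 2625 lower) and 9 lists. Of all 5350 calls of the main setting, 3421 passed in the same direction without control replicate 1. The 88 named genes were chosen for large changes that passed in the main setting, which favours keeping their side. Of their 1215 values under alternatives, 1190 kept direction and side, 24 no longer passed and 1 turned, ASNS at -0.23 with _x_at and _s_at probe sets left out. Sizes moved more: the log2 change of 25 of the 88 was over 1.5 times smaller as the mean of a gene's probe sets (GREB1 -1.24, SLC7A2 -1.36, DCN -1.86, AGR2 1.68, WFDC2 0.85, TNC 0.51, ERN1 0.40, HK2 0.39, IFIH1 0.38 and BUB1 0.27 among them), and that of 10 of 73 smaller or reversed with _x_at and _s_at probe sets left out. Of 320 list values 305 kept both, 11 lost and 3 gained a call. The fibroblast list turned by fry, down with a median of -0.0106 (adjusted p = 0.00443, highest of the alternatives 0.997), a test on the list's own genes, among them DCN. Apart from these constructions the cause was not tested. Dim probe sets carry little signal over background, which limits what they can show.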

Other observations

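The tests on DCN and on the mitosis list were chosen only after their results were seen, as were the genes in the next paragraphs, the comparison of probe sets with no gene named, and the neighbour tests on plain probe sets and on lower genes of unlike stems; the other tests on neighbours, those on gene families and the splits of the arrays were not.

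ERBB3, a receptor of the EGF receptor family without much kinase activity of its own, rose from 6.30 to 9.18 (log2 difference 2.88, SE 0.08, adjusted p = 4.73e-08, limma with Benjamini-Hochberg adjustment), on 3 of its 5 probe sets. EGFR fell by 0.44 on the brightest of 9 probe sets, 2 of which fell, and ERBB2 (-0.18) and ERBB4 (0.04) did not pass. GALNT genes encode the transferases that start mucin-type glycosylation. Of 18 measured genes of that stem, 6 rose and 2 fell, with GALNT10 at 2.38 (SE 0.10), GALNT6 at 1.68 (SE 0.12) and GALNT3 at 1.26 (SE 0.09). The 18 include the divergent transcript GALNT7-DT, which is not a transferase gene and did not pass. Among 11 measured complement genes, 6 fell and 1 rose. The early components C1R (-1.52, SE 0.10) and C1S (-1.40, SE 0.15), C3 (-1.31), the inhibitor CFI (-1.22, SE 0.09) and the surface regulators CD55 (-0.65) and CD46 (-0.30) fell, while CFB of the alternative pathway rose by 1.68 (SE 0.10).

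Among probe sets with no gene named, the balance of directions differed from that of probe sets with a named gene. Of 537 that changed, 185 were higher and 352 lower with PDEF, 34.5% higher, against 2584 higher and 2051 lower, 55.7% higher, among changed probe sets of a single gene. Under median centring the shares were 40.4% and 60.5%, and under quantile normalization 35.9% and 52.9%. No explanation was tested.

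Families were taken as genes whose symbols share a stem, and 348 stems with at least 8 measured genes were tested by Fisher's exact test. The hypothesis that some families hold more risen genes than other genes do was met by 0 stems after adjustment (24 at an unadjusted p under 0.05); the lowest by unadjusted p were GALNT and KLK, with 5 of 14 KLK genes up, at an adjusted p of 0.228 that CHMP, CPNE and KIF share. For falls, 1 stem passed, that of the metallothioneins, zinc- and copper-binding proteins, with 8 of 10 down (adjusted p = 2.25e-06). MT1F (-0.85), MT1X (-0.80), MT1G (-0.70), MT1H (-0.62), MT1E (-0.61), MT1HL1 (-0.58), MT2A (-0.55) and MT4 (-0.42) fell. Of the 10 genes, 7 were measured on _x_at or _s_at probe sets, which related metallothionein transcripts share, so the number of separate genes that fell is open. On plain probe sets MT4 passed, and MT1G (-0.20), MT1M (-0.18) and MT3 (-0.15) did not.

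DCN fell by 3.59 although decorin is a fibroblast product, so fibroblasts in the control cultures were tested as a candidate source. The other 14 fibroblast markers had a median change of -0.000201 (SD 0.28). Only 5 of all 15 lay above the arrays' highest median in the controls, and dim ones could hardly fall, so that median decides little. COL1A2, COL3A1 and LUM, abundant in fibroblasts, reached at most 3.37 in the controls, under the array median of 3.77, which argues against such cells. Other transcripts bound by the DCN probe sets were tested next, and of the 4 probe sets outside the _x_at and _s_at types the brightest, 209335_at, fell by 2.36, which argues against them as the whole cause; the other 3, dim at 2.51 to 2.89 in the controls, did not pass (0.00, 0.19 and -0.23). A response of the epithelial cells themselves to PDEF remains as a hypothesis, found and tested on the same data.

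The rise of the mitosis list may come from a single array, from scaling, or from how far the separate cultures had grown. Its median change was at least 0.47 with each array left out in turn, which argues against the first. Scaling would move other genes of the same mean level alike, but 10000 sets drawn from them had medians of -0.20 to 0.19 against 0.55 for the list, which argues against it. Per array the list averaged 6.41, 6.68 and 6.65 in the controls and 7.23, 7.22 and 6.97 with PDEF (exact two-sided permutation test, p = 0.1, the smallest possible). The groups did not overlap, and fry, which uses the spread between arrays, called the list up (adjusted p = 0.0170). The exact test cannot go below 0.1, and the list was chosen after its rise was seen. Chance differences in growth between single cultures were therefore not excluded. Growth that differed between the groups as a whole cannot be told apart from an effect of PDEF on division, since each culture belongs to 1 group.

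Genes over 2-fold higher with PDEF lay next to each other, by order along the chromosomes in the reference gene table, in 10 pairs against 4.99 by chance (p = 0.0306 over 10000 permutations). Genes over 2-fold lower did so in 7 pairs against 1.27 (permutation p = 2e-04). The values argue against chance placement for the lower genes. For the higher genes, at a permutation p of 0.0306, they do so weakly. In the simulation 2 of 20 random sets passed 0.05, too few sets to judge the error rate of the test. Without pairs of 1 symbol stem, 4 pairs of higher genes remained against 4.64 (permutation p = 0.687), so that excess rests on 6 pairs of related genes, among them KLK5 to KLK10 and SERPINB3 with SERPINB4. Signal shared between related genes cannot be told apart from joint regulation: 4 of the 6 pairs stood on plain probe sets too, but all 6 pairs of higher genes left there, against 3.48, gave a permutation p of 0.14. The lower pairs included C1S with C1R, IFI44L with IFI44, TNFSF14 with C3 and SLC7A2 with PDGFRL, and 5 pairs of unlike stems remained against 1.21 (permutation p = 0.0077). The lower pairs were not counted on plain probe sets, and C1S, C1R and IFI44 stood on _s_at ones. Joint regulation of such neighbours is a hypothesis, and no further test was run.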
